A study of Arabidopsis thaliana with 2 samples.

How the data were processed

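TOC1 ChIP-seq and input libraries, 1 each, were sequenced from Arabidopsis seedlings. Per the labels' protocols, TOC1-DNA complexes were isolated from sonicated nuclei with an anti-GFP antibody and sequenced for 36 cycles on a Genome Analyzer II. Per the deposited description, reads were trimmed to 25 nt and mapped with ELAND to TAIR9, and regions were called with ERANGE 3.1. Per the file headers, regions needed more than 4 RPM and a ratio over 4, 181 further regions failed a directionality filter, and 35 regions found in the background gave an FDR of 3.42 percent. The region list holds the authors' RPM (reads scaled to the size of the ChIP library), the authors' fold over input (a ratio), percent of reads on the plus strand, a deposited peak height (signal) and the authors' p-value. The deposited percent of multireads was 0 in every region. How the reads in the deposited position files were chosen from the ELAND output is not given in the sources used here.

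The ELAND output held 14244345 ChIP reads, of which 11356319 matched nowhere, and 13151784 input reads, of which 4159640 matched nowhere. The position files held 1881165 and 5738780 reads, of which 2.16% and 9.40% lay on the plastid genome. Chromosomes 1 to 5 were used, with 1840450 and 5199158 reads; keeping 1 read per position and strand removed 2.73% and 4.95%. Reads were counted at their 5' end, as raw counts, and ratios were multiplied by 2.82, the quotient of the totals. Shares have Clopper-Pearson intervals, ratios exact conditional binomial intervals and densities exact Poisson intervals, all at 95%. They cover counting error only, since amplified reads are not independent molecules. No input read at a region gives no ratio, only a lower limit.

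No genome sequence was used here. Names came from a RefSeq gene table of assembly TAIR10.1, whose build differs in name from that of the reads, so none of its coordinates are printed. Positions were tested against each other: sequence was rebuilt from the mapped 25 nt reads, and its GC content was aligned with the gene spans. The best lag was at most 10 bp on each chromosome and within 100 bp in all 116 segments of 1 Mb. The rebuilt sequence covered 65.0% to 66.6% of chromosomes 1 to 5. The table gives no gene direction, so direction was inferred from codon and 6-mer models of the rebuilt sequence. The models gave the same direction for 87.0% of genes, and for 97.5% of the 17814 genes clear under both. The 6-mer model was trained on genes called by the codon model, so this agreement is no independent check. TATAAA lay 20 to 45 bp outside 4.15% of inferred 5' ends and 1.97% of inferred 3' ends. Distances from a gene start rest on this inference. The design foresaw exons, introns and UTRs; these classes were replaced by upstream, gene, downstream and other. Motifs are given per kb searched, because windows at summits were better covered than flanks. The design's ranking score was taken to be the authors' fold.

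A gene had a region where one overlapped by 1 bp or more the span from 1000 bp upstream to 500 bp downstream of its start. Lists (8, with 114 genes, all found in the table) and families (11, matched by name and synonym) were set beside 10000 random lists matched on the quintile of upstream distance. Region positions were set beside 1000 random placements, and motifs (16) beside windows moved 2000 bp and 1000 sets of random promoter windows. Percentiles describe these libraries and are not p-values. The genes named are every member of the 2 clock lists, members of other lists with a region, genes nearest the 20 regions highest by fold, and TOC1; this rule, the lists and the alternatives not marked below were fixed before the data were examined. Extremes of a list are also named, and so is CBF3, chosen after its value was seen. From the families, which the rule does not cover, genes were chosen after their values were seen.

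The functions were tested on simulated data. Of 1024 simulated regions at a true ratio of 1, the interval lay above 1 for 1.17%; at a ratio of 2 for 26.9% and at 5 for 92.8%. The mean percentile of 1000 chance lists was 51.4. Over 100 simulations of a motif planted at 4 times the flank density, with uneven coverage, the mean recovered was 4.10 (SD 0.661) and 95% of the intervals held the planted value. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives were repeated reads removed, single-hit ELAND reads, other scaling, shifted reads, other reaches and windows, the regions with the higher fold, and, chosen after seeing the data, regions with p at or under 0.001, gene spans without direction, genes of clear direction, sequence from the input alone and regions other than wide ones inside genes.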

Results

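Chromatin bound by TOC1, a pseudo-response regulator of the Arabidopsis circadian clock that peaks in the evening, was profiled by ChIP-seq in seedlings. The line carries a TOC1 minigene (genomic TOC1 fused to YFP) in the toc1-2 mutant, so that an anti-GFP antibody recovers the fusion. Seedlings were grown for 2 weeks in cycles of 12 h light and 12 h dark and collected at Zeitgeber time 15, that is 15 h after lights on. There was 1 ChIP library and 1 input library, the input being DNA without immunoprecipitation. With no replicates, no test between conditions is given. Intervals are 95% intervals that cover counting error only, and each comparison describes these 2 libraries. The deposited read positions on chromosomes 1 to 5 numbered 1840450 for the ChIP and 5199158 for the input. Ratios of ChIP to input reads are scaled by these totals. Coordinates are on TAIR9, and RPM, fold and p-values of regions are the authors' own.

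The question of the series was where in the genome TOC1 binds. TOC1 itself comes first, since the line carries it as a transgene. No region lay at the TOC1 promoter (AT5G61380), from 1000 bp upstream to 500 bp downstream of the inferred gene start. Its promoter had 36 ChIP and 41 input reads, a scaled ratio of 2.48 (1.54 to 3.98). One deposited region lay inside the gene, on chromosome 5 from 24676490 to 24676717, with 34 ChIP and 24 input reads and a ratio of 4.00 (2.3 to 7.05). The gene span held 468 input reads, a density 2.38 times that of the median gene (2.17 to 2.6) and at the 99.8th percentile of genes. Read density in both libraries was therefore raised over this gene. Its region is described separately here, but the counts and medians below include the region and the gene. The raised density followed blocks of the gene.

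**Figure D1:**
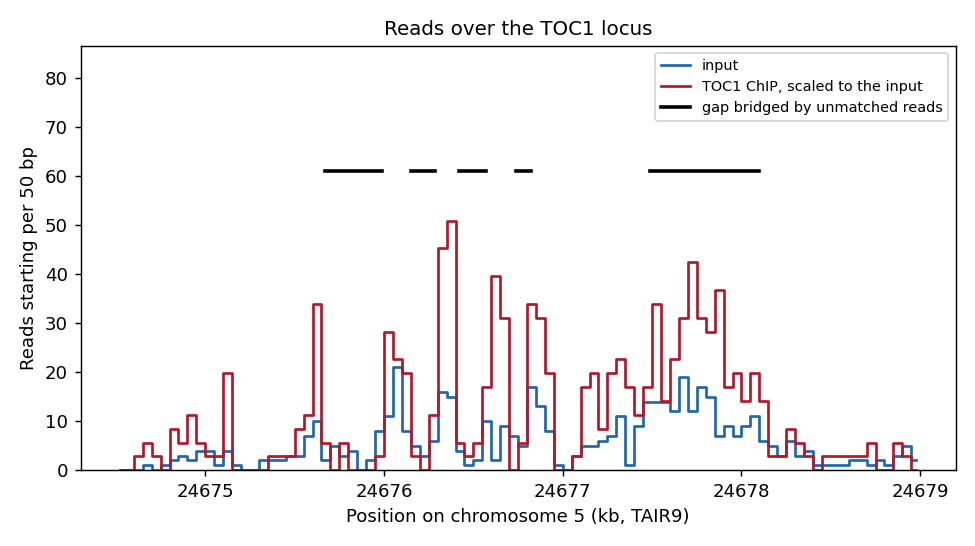
Reads over the TOC1 locus on chromosome 5: the x axis is position in kb on TAIR9, the y axis is reads starting per 50 bp, for the input (blue) and for the ChIP scaled to the input (red). Black bars mark gaps bridged by reads that matched nowhere as a whole; reads were dense in blocks beside the gaps, except that the longest gap, of 609 bp and bridged by 1 ChIP read, spans a densely covered stretch.

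The authors' list held 1024 regions, with a median width of 235 bp, a median of 6 RPM and a median fold of 5.1. ChIP reads in the regions made up 1.62% of the library (Clopper-Pearson 1.60 to 1.64), against 0.345% of the input (0.340 to 0.351), a ratio of 4.70 (4.61 to 4.79). Counted region by region, the median scaled ratio was 4.44, and for 1022 of the 1024 regions the interval lay above 1. The regions were selected by the authors on these same reads for a fold of at least 4, so this count describes the list and is no independent check of it. The depth per region was low: the median region held 15 ChIP and 10 input reads. The description deposited with the data gives a p limit of 0.001, while p-values in the list reached 0.0092, and 572 regions were at or under 0.001.

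Regions lay upstream of genes more often than randomly placed intervals of the same widths. Midpoints of 251 regions, 24.5% (21.9 to 27.3), fell within 1000 bp upstream of a protein-coding gene, against a median of 13.4% over 1000 random placements (central range 11.4 to 15.6), 1.83 times as many. Within genes lay 526 regions, 51.4% (48.3 to 54.5), against 56.3% in the placements. Downstream within 1000 bp lay 94 regions, 9.18% against 6.64%. The other 153 regions, 14.9%, were farther from genes, against 23.5%. A placement needed only to hold an input read, while the median region held 10, so placements were not matched on coverage. Gene direction was inferred from rebuilt sequence, and exons, introns and UTRs were not distinguished.

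**Figure D2:**
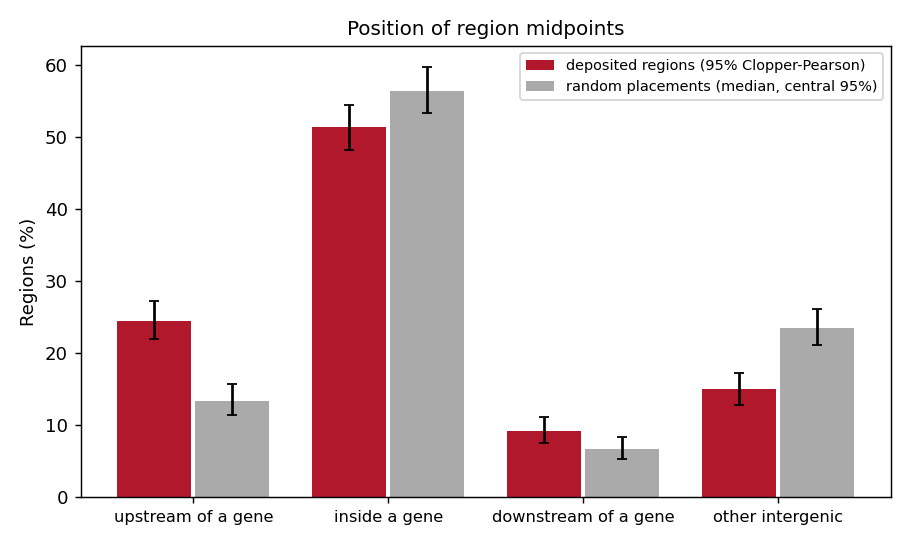
Share of region midpoints (y axis, percent) in 4 position classes (x axis) for the 1024 deposited regions (red, 95% Clopper-Pearson interval) and for 1000 random placements (grey, median and central 95%). Regions upstream of a gene made up 24.5% against 13.4% in the placements.

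A region lay at the promoter of 641 of 27444 protein-coding genes, 2.34%. Core clock genes were far more often among them. They form 2 lists named by phase, and the phase of their members was not measured here. Of the 14 clock genes listed as morning-phased, 7 had a region, where random lists matched on upstream distance had 0.334 on average (100th percentile of 10000 lists). These 7 were CCA1 and LHY, the paired MYB-like repressors of the morning, the pseudo-response regulators PRR9 and PRR7, the MYB-like genes RVE4 and RVE7, and LNK2, a coactivator that acts with RVE proteins. PRR9 (AT2G46790) had the highest promoter ratio of the list, 5.02 (3.29 to 7.78), from 64 ChIP and 36 input reads, and 2 regions. The stronger of these ran from 19232348 to 19232596 on chromosome 2, with 10.8 RPM and a summit 203 bp upstream of the inferred gene start. At PRR7 (AT5G02810) the ratio was 3.46 (2.41 to 4.98), with a region on chromosome 5 from 641898 to 642381 and a fold of 8.2. The LHY region (AT1G01060, chromosome 1, 37730 to 38260) had 25.9 RPM, and the LHY promoter ratio was 3.37 (2.37 to 4.8). The CCA1 region (AT2G46830, chromosome 2, 19245179 to 19245656) had 14.4 RPM, with a promoter ratio of 2.82 (1.89 to 4.23). Promoter ratios were 2.57 at RVE7 and 2.01 at LNK2. At RVE4 the ratio was 1.32 with an interval that included 1 (0.91 to 1.87), although a region of 4.4 RPM lay there.

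Among the 7 morning-phased genes without a region, RVE2 had a ratio of 2.82 (1.65 to 4.85), RVE8 1.91 (1.32 to 2.75), LNK1 1.90 (1.2 to 2.97) and PRR5 1.86 (1.05 to 3.23). RVE1 had 1.21 (0.61 to 2.27) and RVE6 1.07 (0.53 to 2.02). The lowest was PRR3, 0.549 (0.21 to 1.25), from 7 ChIP and 36 input reads. Binding at these last 3 promoters was not detectable at this depth. For 10 of the 14 genes the interval lay above 1, against 8.10% of all genes. It also lay above 1 for 4 of the 12 reference genes, a control list, and for 3 of the 13 evening-phased genes.

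Of the 13 clock genes listed as evening-phased, 3 had a region, against 0.306 in random lists (99.9th percentile). GIGANTEA (GI, AT1G22770), which links the clock to photoperiodic flowering, had 2 regions and the highest ratio of this list, 3.70 (2.57 to 5.35), from 72 ChIP and 55 input reads. The stronger GI region, chromosome 1 from 8060610 to 8061016, had 23.2 RPM and a summit 951 bp upstream. The other members with a region were LUX and ELF4, which together with ELF3 form the evening complex. The LUX ratio was 1.79 (1.25 to 2.53) and the ELF4 ratio 1.51 (0.99 to 2.29). ELF3 had no region and a ratio of 0.94 (0.50 to 1.69). The members BOA, JMJ30, GRP7, GRP8, FKF1 and CHE had no region and ratios from 1.09 to 1.55, with intervals that reached 1 or below. The F-box genes ZTL and LKP2 had the lowest ratios of the list, 0.682 (0.35 to 1.24) and 0.77 (0.46 to 1.24).

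**Figure D3:**
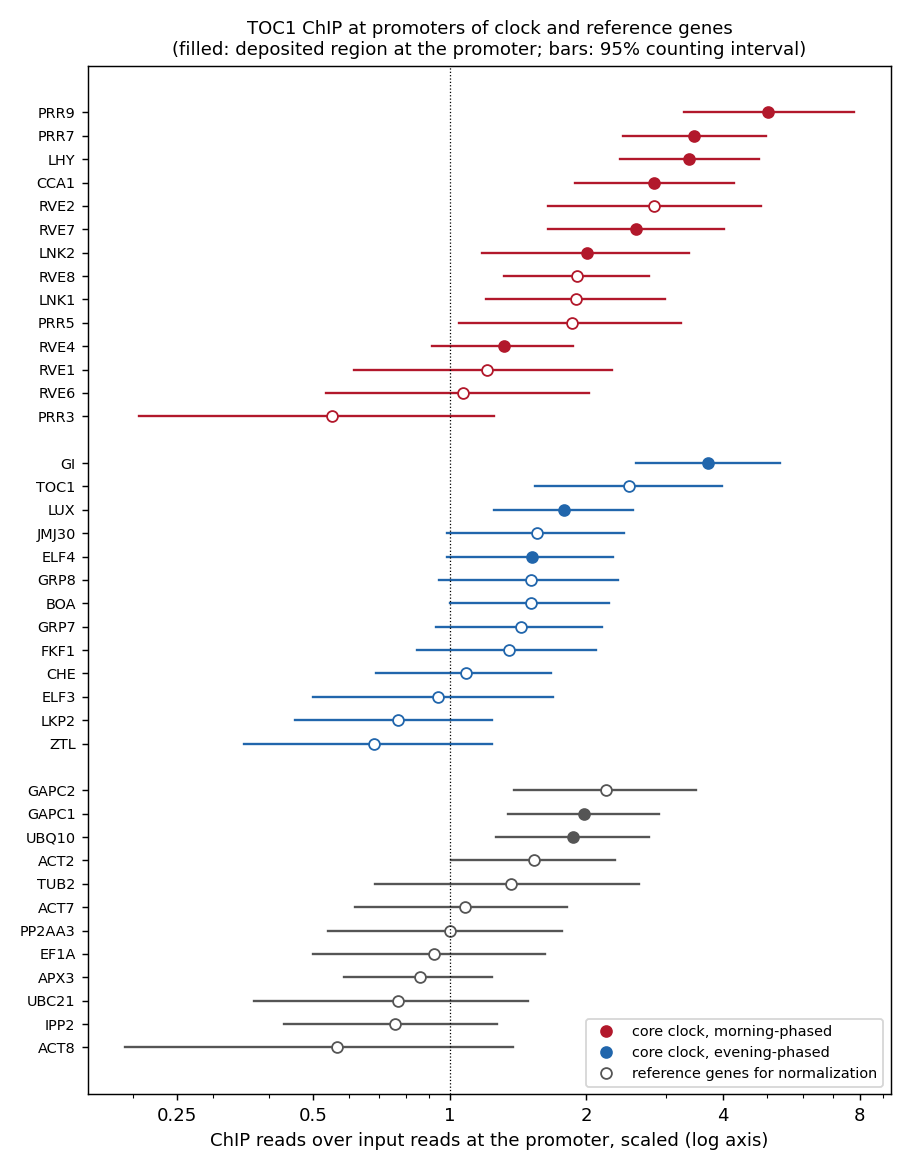
Scaled ratio of ChIP to input reads at the promoter (x axis, log scale) for each clock gene and reference gene (y axis); bars are 95% counting intervals and filled points have a deposited region. PRR9 was highest at 5.02, and the reference genes GAPC1 and UBQ10 also had a region.

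Outside the clock, regions occurred at light signalling and cold response genes. In the light perception list 4 of 20 genes had a region, against 0.468 in random lists (99.9th percentile). They were PIF4 and PIF5, bHLH factors that promote growth in the dark, with ratios of 3.11 (2.08 to 4.68) and 3.08 (2.18 to 4.37), the photoreceptor gene PHYB at 2.08 (1.31 to 3.26) and HY5 at 1.65 (1.1 to 2.47). The direction of PIF4 was not clear from its sequence. In the cold response list 3 of 13 genes had a region (99.8th percentile). These were the zinc finger gene ZAT12, with a ratio of 3.40 (2.49 to 4.66), and the neighbouring cold regulators CBF1, 2.97 (1.87 to 4.73), and CBF2, 2.82 (1.88 to 4.25). Their neighbour CBF3, named outside the rule, had a similar ratio without a region, 2.74 (1.66 to 4.53). The promoter span takes in the first 500 bp of a gene. Gene-span ratios, which share those reads, were 3.27 (2.41 to 4.45) at ZAT12, 2.57 (1.63 to 4.03) at CBF2, 1.72 (1.13 to 2.6) at CBF1, 1.99 (1.53 to 2.57) at PIF5 and 1.78 (1.34 to 2.35) at PIF4. KIN1 was the lowest of the list, 0.461 (0.19 to 0.98). In the flowering list 1 of 15 genes had a region, COL1, with 1.57 (1.13 to 2.17). In the abscisic acid list 1 of 14 had, CHLH, with 2.48 (1.66 to 3.69). None of the 13 light-harvesting genes had a region. The list of 12 reference genes, chosen as a control, had 2 with a region, UBQ10 at 1.87 (1.27 to 2.74) and GAPC1 at 1.98 (1.34 to 2.89), and stood at the 98.5th percentile. Both of those regions were above the p limit of 0.001, and under it no reference gene had a region at the promoter. A region with p 0.00014 lay inside a further reference gene, GAPC2, on chromosome 1 from 4608839 to 4609064. The same limit left 4 morning-phased and 3 evening-phased clock genes, 4 light perception genes, 3 cold response genes, 1 abscisic acid gene and 0 flowering genes with a region.

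Median promoter ratios do not depend on the called regions. The median was 1.96 for morning-phased clock genes (100th percentile of random lists) and 1.51 for evening-phased ones (99.955th percentile). It was 1.55 for cold response, 1.52 for flowering, 1.34 for light-harvesting, and 1.25 for both light perception and abscisic acid signalling. The abscisic acid list lay at the 95.4th percentile, below the limit of 97.5 used here, while the others just named lay above it. It passed that limit with 1 read kept per position and strand (98.6) and with the span from 500 bp upstream to 250 bp downstream (99.3). The reference genes had a median of 1.04, at the 57.5th percentile. Over all genes the median was 1.02. In the span from 500 bp upstream to 250 bp downstream the reference genes had 1.26, at the 85.9th percentile.

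Gene families were matched by name, which also missed members. The bHLH genes PIF4 and PIF5, which had a region, were not among the genes matched as bHLH proteins. Counts below therefore hold for the matched members only, not for whole families. B-box zinc finger proteins, several of which act in light signalling, had 7 of 31 members with a region (100th percentile), and 4 with p at or under 0.001 (99.985th percentile). Among the members with a region, BBX29 was highest, 2.53 (1.71 to 3.75), and STH lowest, 1.21 (0.82 to 1.75). Ethylene response factors had 3 of 30 (98.7th percentile), with ERF4 at 3.99 (3.02 to 5.28), but fell below the limit with an upstream reach of 3000 bp (92.9) and among the regions with the higher fold (82.2). The summits at these 3 genes lay inside the gene, that of ERF4 698 bp from its start in a region 1505 bp wide, and gene-span ratios were 6.13 at ERF4, 2.31 at ERF5 and 2.00 at AT5G51190. The remaining families lay below the limit: 3 of 72 WRKY factors, 4 of 104 NAC proteins, 4 of 136 MYB proteins, 2 of 112 auxin response genes, 1 of 34 bHLH proteins, 1 of 67 ribosomal proteins, 2 of 58 genes matched as heat shock proteins, and none of 5 Dof or 13 pentatricopeptide repeat proteins. Some matches by name went beyond the family: ARF19 among the auxin genes is an auxin response factor, HSFA3 is a heat shock transcription factor, and HSPRO2 is not a heat shock protein. In all, 7 of the 19 lists and families lay at or above the 97.5th percentile, among them the reference genes, a control list.

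Ranked by the authors' fold, the 20 leading regions were narrow and rested on few reads, 9 to 25 in the ChIP and 0 to 5 in the input, and 14 of the 20 were above the p limit of 0.001. The highest fold, 42.2, belonged to a region on chromosome 4 from 15292383 to 15292633 near WRKY11, with 13 ChIP reads and no input read, for which the lower limit of the ratio was 8.61. Next were regions near BBX32, AT4G37608, CYP707A3, an abscisic acid catabolic gene, and ACA1. The other regions of the 20 lay nearest BZO1, TKI1, RBOHD, a NADPH oxidase gene, AT3G60310, CRF10, AT2G47485, AFB5, MPK15, CHIA, WRR4, EDA12, PIP1B, WNK1, BME3 and AT5G47380. The lowest ratio among the 20 was 8.47, near AFB5 and BME3. Their order is not resolved at this depth, since intervals of these regions overlapped widely: that at BBX32 ran from 3.77 to 155.9.

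**Figure D4:**
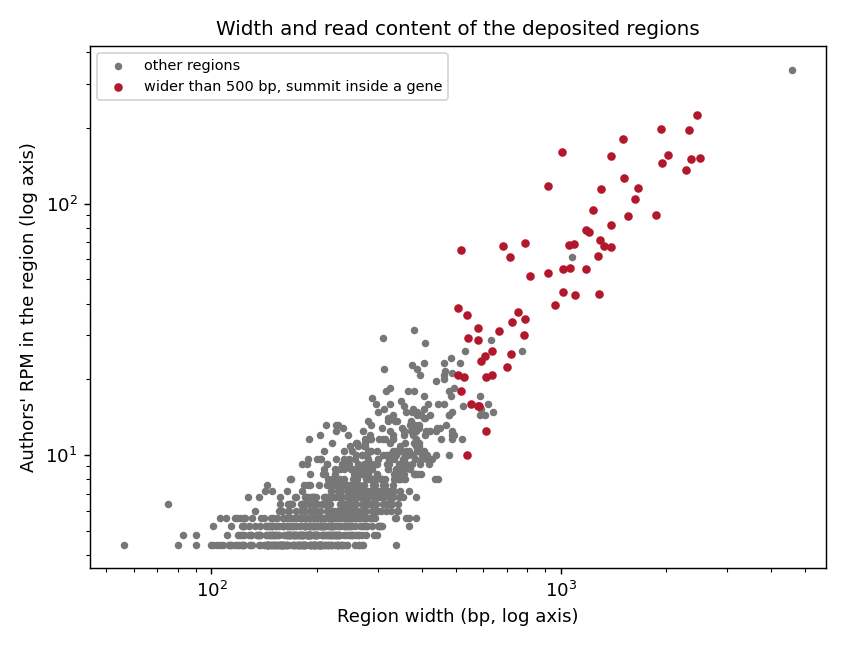
Width of each deposited region (x axis, bp, log scale) and the authors' RPM in it (y axis, log scale); red points are the 66 regions wider than 500 bp with a summit inside a gene and grey points all others. The red points reached 225.9 RPM and the widest region, a grey point, 340.9 RPM, whereas the 20 regions with the highest fold had 4.4 to 10 RPM.

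G-boxes (CACGTG), bound by bZIP and bHLH factors, were concentrated at the summits. Within 250 bp of a summit they occurred 0.967 times per kb searched, against 0.234 in windows moved by 2000 bp, a ratio of 4.13 (3.39 to 5.05), and 25.3% of the windows held at least 1, against 6.05% of the moved ones; these shares, unlike the densities, are not corrected for the better coverage of windows at summits. All 1000 sets of random promoter windows had a lower density. The overlapping ABRE core had a ratio of 4.02 (3.32 to 4.88), the TCP-binding site 5.16 (3.12 to 8.90) on 65 occurrences (11.1 within 100 bp of the summit), and the protein box 2.35 (1.71 to 3.24). The morning element was at 1.56 (1.28 to 1.89), the hormone up at dawn element at 1.26 (1.07 to 1.47) and the short TGTG core at 1.11 (1.07 to 1.16). The morning element varied with the setting. It was at 2.24 within 100 bp of the summit, but at 1.14 among regions with the higher fold, where its reversed sequence was at 1.08. The hormone up at dawn element was not distinguishable from 1 among regions with p at or under 0.001, 1.13 (0.908 to 1.41), or inside genes, 0.953 (0.752 to 1.2). The evening element, the CCA1-binding site, the short evening element, the GATA motif and the telo box had intervals against the moved windows that included 1. The evening element stood at 1.46 (0.79 to 2.70) on 22 occurrences. Against the random promoter sets, the evening element lay at the 98.6th percentile, the short evening element at the 98.7th, the CCA1-binding site at the 94.9th, the GATA motif at the 92.7th and the telo box at the 0.1th, with 0.535 times their density. At regions upstream of genes the short evening element had a ratio to moved windows of 2.42 (1.52 to 3.86), and inside genes 0.846 (0.586 to 1.21). The 4 reversed sequences used as controls had ratios from 1.02 to 1.24, each with an interval that included 1. G-box density was highest at regions upstream of genes, 1.71 per kb (1.44 to 2.02), and lower at those inside genes, 0.507 (0.413 to 0.616). Relative to their own moved windows, both were raised, 5.90 times (4.2 to 8.42) upstream and 2.69 times (1.94 to 3.77) inside genes. About 65% of the bases of each chromosome could be searched.

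**Figure D5:**
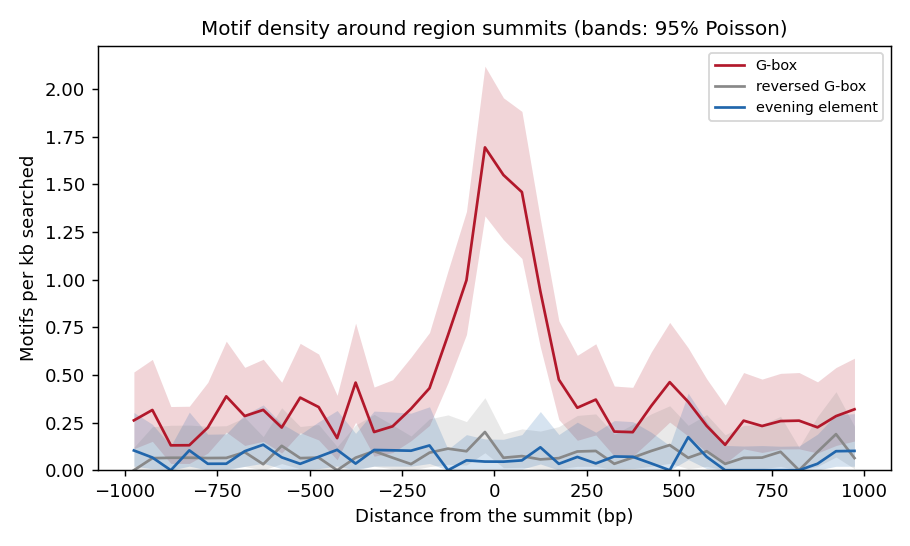
Motifs per kb searched (y axis) in bins of 50 bp by distance from the region summit (x axis, bp) for the G-box, its reversed sequence and the evening element; bands are 95% Poisson intervals. G-box density was highest in the bins on either side of the summit, 1.69 per kb (1.33 to 2.12) and 1.55 (1.21 to 1.95). The other sequences showed no such peak.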

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

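Both tests of this part were chosen after the result was seen. Of the ChIP reads, 79.7% matched no place in the genome, a signal outside the mapped reads used above, against 31.6% in the input. An exact stretch of adapter sequence was found in 9.31% of the unmatched ChIP reads. The search missed adapter reads with an error in that stretch or with a short adapter tail, so this share is a lower limit. Sequencing errors beyond 2 mismatches should leave base composition unchanged, but the other unmatched ChIP reads were 61.3% GC and the matched ones 43.6%, a difference of 17.8 percentage points; in the input the values were 52.9% and 43.4%. Errors alone therefore do not account for them. Reads from another organism were not tested here and stay open, and no biological explanation was tested. These reads do not enter the ratios, but they lower the depth of the ChIP.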

How the results depend on the processing

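There is 1 library per group, so no replicate could be left out and no splits of samples exist. No paired analysis was possible because each group has 1 sample. Of 211 alternative values, 163 were labelled as not changed. The label does not mean an equal value or measure the size of a change. It was given to 825 regions with an interval above 1 against 1022, and to 524 genes with a region against 641. The ratio of reads in regions, 4.52 against 4.70, was labelled as moved. Of the 175 alternative values that belong to single lists or motifs, 39 were labelled as moved, and none with an interval clear of 1 changed side. The morning element went from 1.56 to 1.14 for the higher fold and to 2.24 with 100 bp windows, and the TCP-binding site from 5.16 to 11.1 with 100 bp windows. With 100 bp windows 3 motifs whose intervals included 1 went from above 1 to below it: the CCA1-binding site (1.37 to 0.581), its reversed sequence (1.02 to 0.587) and the reversed evening element (1.24 to 0.353). With 1 read per position and strand, the ratio of reads in regions was 4.52. With a reach of 3000 bp, 36.2% of regions lay upstream (random placements 23.7%) and 1140 genes had a region, since more sequence counts as promoter. The regions with the higher fold gave 336 genes and a G-box ratio of 5.09, and windows of 100 bp gave a G-box ratio of 6.33. Chosen after seeing the data, the p limit of 0.001 left 572 regions with an interval above 1 and 394 genes, by construction, since it keeps 572 regions, and gene spans with 1000 bp on both sides gave 1159 genes. For the 100 bp windows and for the higher fold, the cause of the change in the G-box ratio was not tested; nor was that for repeated reads. Reads shifted by 100 bp left 825 regions with an interval above 1, against 1022. The number of lists and families at or above the 97.5th percentile was 5 to 8 over the alternatives, against 7. The reference genes fell below that limit with the 3000 bp reach (95.5), the higher fold (92.9) and the p limit (42.2), and stayed above it with gene spans without direction (99.4, 3 of 12 genes) and with unmatched random lists (98.1). The ethylene response factors fell below it with the 3000 bp reach (92.9) and the higher fold (82.2). NAC proteins rose above it with gene spans without direction (99.3). Depth limits single regions: at region depth in simulated data, a true ratio of 2 was seen above 1 in 26.9% of cases.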

Other observations

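The tests of repeated reads and of G-boxes, and that of extra TOC1 copies, were chosen after the result was seen, and the genes named here were chosen after their values were seen. The authors' RPM counts all reads in a region and is not divided by its width, so ranking by it favours wide regions. Ranked by RPM in place of fold, the leading regions were wide, and 19 of the first 20 had their summit inside a protein-coding gene. The first, on chromosome 1 from 29804926 to 29809524, had 340.9 RPM and a ratio of 6.60 (5.83 to 7.48), with its summit in a transcribed pseudogene, AT1G79245. The others lay in genes such as the zinc finger genes SZF1 (225.9 RPM, 5.42) and STZ (160.1 RPM, 6.14), ERF4 (180.0 RPM, 6.17), the ethylene synthesis gene ACS6 (155.3 RPM, 5.43), the deadenylase gene CAF1a (117.8 RPM, 6.86) and RRTF1 (89.8 RPM, 3.78). No list was fixed for these genes, and no shared function was tested. WRKY40 had a ratio of 6.41 (5.18 to 7.96) over its gene span, against 2.88 at its promoter.

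The 66 regions wider than 500 bp with a summit inside a gene were 6.45% of the regions and held 39.1% of the ChIP reads in regions. They also held 6867 of the 17960 input reads in regions. Their median width was 988.5 bp, against 228 bp for the other regions. Their ratio of 4.81 (4.67 to 4.96) was near the 4.63 (4.52 to 4.74) of the other regions. The large share of ChIP reads thus came with a large share of input reads. High transcription alone was tested on 67 genes matched by name as cytosolic or organellar ribosomal proteins. Their gene bodies had a median ratio 0.928 times that of all gene bodies (bootstrap 0.887 to 1.02), below the 1.3 set in advance. These genes as a set were therefore not raised. Transcription was not measured here, so the test cannot decide whether highly transcribed genes were recovered. Light-harvesting gene bodies had 1.15 (1.144 to 1.32) and ethylene response factors 1.23 (1.05 to 1.63), relative to all gene bodies. The reference gene UBQ10 had a body ratio of 2.75 (2.25 to 3.38). For tRNA genes with 250 bp either side the value was 1.15 (1.08 to 1.22), also below 1.3. With 1 read per position and strand the ratio in the wide regions was still 4.59 (4.45 to 4.73), which argues against amplification. G-boxes were at 0.459 per kb (0.251 to 0.770), below the 1.71 of regions upstream of genes and near the 0.516 (0.413 to 0.636) of narrower regions inside genes. Over their own moved windows, however, they were 2.98 times as dense (1.07 to 9.45), an interval that overlaps the 5.90 (4.2 to 8.42) upstream, so sequence-specific sites are not excluded. Input reads, taken without immunoprecipitation, were also dense in the wide regions. Their median was 88 at a median width of 988.5 bp, against 55.4 per kb over all gene spans. Recovery of such genes without TOC1, for example through open chromatin or their transcription at harvest, therefore stays open. No control immunoprecipitation was analysed here, and the pattern is not called biological.

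At TOC1 the input density was 255.0 reads per kb in blocks joined by unmatched reads and 67.1 (41.0 to 103.7) in the gaps, a quotient of 0.263, against 55.4 over all gene spans. Extra genomic copies that include the gaps would raise blocks and gaps alike. Such copies do not account for the raised blocks, although a smaller gain over the whole gene is not excluded. A genomic copy that lacks the gaps would raise the blocks alone, so this comparison cannot exclude it. Unmatched reads joined pieces of TOC1 in forward order 14 times, 8 in the ChIP and 6 in the input, and 0 times in reverse order, while the other 26 clock genes together gave 8 forward and 11 reverse joins. The blocks and gaps used were those at the 3 joins seen in at least 2 reads; a join seen in 1 read spans 609 bp of densely covered sequence and does not follow the blocks. The forward joins are consistent with spliced TOC1 coding sequence among the templates of both libraries, as a hypothesis; its source was not tested. The blocks had a ChIP to input ratio of 2.77 (2.08 to 3.68), and the deposited region inside TOC1 overlaps the block that starts at 24676571.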
